A study of Drosophila melanogaster with 6 samples.

How the data were processed

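Total RNA from the fat bodies of 6 pools of Drosophila melanogaster larvae was measured, 3 of homozygous srl1 mutants and 3 of the genetically matched control, each on 1 Affymetrix array. Per the labels' protocols, each pool held 20 fat bodies of larvae 5 days old, and 30 ng of total RNA per sample went through a labelling procedure with 2 rounds of amplification. The protocol text speaks of mutant larvae for all 6 samples; genotypes were taken from the source label of each sample, which names srl1 or the unmutated allele. The series design text gives 3 biological replicates per genotype.

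The deposited values were 1 intensity per probe set on a linear scale for 18952 probe sets. The submitters' processing notes name GCOS 1.4 and MAS5; scaling, background settings and detection calls are not given in the sources used here. The table was expected to be scaled to a common target already, and the values showed that it was not: the deposited trimmed mean (2% removed at each end) was 46.5 on mutant array 1 and 97.0 to 125 on the other 5 arrays, and the mean of the cre spike-in probe sets was 4342 on that array and 8018 to 10066 on the others. The log2 intensities were therefore quantile normalized between arrays, a choice made before any test was run, and the values as deposited, which the plan had named as the reported setting, became the alternative. Quantile normalization gives every array the same distribution, so a shift of most genes one way would be removed by it.

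The 183 control probe sets were left out of the normalization and the tests. Of the remaining 18769, the annotation table used here gave a single gene symbol for 13647 and several for 402, while 4720 were unlisted and are unnamed here. Of the single symbols, 13544 were brought up to date through their gene identifier in RefSeq. No gene was named from a probe set with several symbols. No probe set was named as srl or w, so the planned report of the srl level was not made. No coordinates were used beyond which genes lie on which chromosome and next to each other in RefSeq.

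Probe sets with a mean log2 signal at or above the 40th percentile were tested, 11261 probe sets for 8935 named genes. Differences are mutant minus control and were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a trend of the variance on the mean), with no covariate, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets. A probe set counted as called at an adjusted p under 0.05. Where a gene had several probe sets, the one with the highest mean signal was used for lists and named genes; 521 genes had several, and in 4 of them probe sets pointed in opposite directions at an unadjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists with 3 or more tested genes, with camera at an estimated correlation and fry beside it. With the preset correlation 11 lists were lower and 4 higher, and with an estimated correlation 0 passed. Of 40 lists fixed, 3 were not tested because under 3 genes were tested: neuron markers, mitochondrially encoded genes and male dosage compensation RNAs. Single values per array were compared by exact two-sided permutation tests, which cannot give a p under 0.1 for 3 against 3.

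The tests, gene lists, alternatives and naming rule were fixed before the data were examined, apart from the normalization and the additions named in the closing part. The rule named srl, the 10 genes with the largest rise and the 10 with the largest fall among called probe sets of a single gene whose mutant and control arrays were separated, up to 4 members of each list of fat body function and up to 2 of each list of another tissue by smallest p, and the marker genes y and w. The alternatives were values as deposited, median centring, an offset of 50 before log2, no filter on dim probe sets, a filter at the 60th percentile, eBayes without trend and with robust estimation, the replicate number as a block, array weights, each array left out in turn, a 1.5 fold minimum, an adjusted p under 0.01, all probe sets of a gene averaged, and 200 instead of 50 neighbours of srl.

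The procedure was tested on simulated data with the means of the real control arrays and limma's moderated variance of each probe set. Log2 changes of 1, 2, 3 and 4 were set in the comparison of srl1 with control, and 11261 probe sets passed the dim filter. Of the changed probe sets that passed the filter it called 21.7%, 78.0%, 95.6% and 100%, and it called 5 of 11087 unchanged ones. Changed probe sets removed by the filter are not in these shares. With oxidative phosphorylation genes shifted, it called 6 of 6 shifted lists and 0 of 31 others. Probe sets varied independently in both simulations, which the genes of a list on real arrays do not. Both simulations may therefore flatter the procedure.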

Results

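Gene expression was measured in the fat body of Drosophila melanogaster larvae, the organ that stores fat and glycogen and combines roles of the vertebrate liver and adipose tissue. Larvae homozygous for srl1, a mutant allele of spargel (srl), were set against larvae of a genetically matched control carrying the unmutated gene. Spargel is the fly homologue of the PGC-1 coactivators, which in mammals regulate nuclear genes of mitochondrial respiration. Each genotype was represented by 3 biological replicates, and each sample was RNA of 20 fat bodies from larvae 5 days old, hybridised to 1 Affymetrix array. The comparison asked which fat body transcripts differed between the srl1 mutant and its control. The number of arrays, 3 per genotype, limits the precision of every value.

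The level of srl itself was not analysed here, because no probe set was named as srl in the annotation used, so the labels were not checked against the targeted gene. The eye colour gene w was likewise not analysed. The body colour gene y had 1 dim probe set, with log2 signals of 1.68, 3.14 and 3.51 on the mutant arrays and 4.97, 2.74 and 4.498 on the control arrays. The deposited signal was lowest on mutant array 1. Its trimmed mean was 46.5, against 97.0 to 125 on the other 5 arrays. After quantile normalization, Pearson correlations ran from 0.936 to 0.954 for the 3 pairs of control arrays and from 0.894 to 0.942 for the 3 pairs of mutant arrays. They were taken across probe sets, which are not independent replicates. The 9 pairs of a mutant and a control array ran from 0.833 to 0.951, and the highest of them was mutant array 2 with control array 3. The log2 ratio of 3-prime to 5-prime signal of the eIF4A control probe sets, a sign of RNA integrity, was 1.54 ± 0.209 (SD, n = 3) on the mutant arrays and 1.10 ± 0.0960 (SD, n = 3) on the control arrays. Every mutant array lay above every control array (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows; 0.3 after Benjamini-Hochberg adjustment over 3 ratios). The GAPDH ratio was 2.10 on mutant array 1, 0.79 and 1.12 on the other mutant arrays and 0.63, 0.89 and 1.001 on the control arrays (exact two-sided permutation test, p = 0.3). The actin ratio gave p = 0.3 by the same exact test.

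Cyp4p2, a cytochrome P450, and nol had the largest falls among the called genes. The log2 signal of Cyp4p2 was 2.35 ± 1.29 (SD, n = 3) in the mutant and 7.87 ± 0.353 (SD, n = 3) in the control, a log2 difference of -5.52 (SE 0.603, limma adjusted p = 0.0102). That of nol was 3.88 ± 0.839 (SD, n = 3) and 9.38 ± 1.002 (SD, n = 3), a log2 difference of -5.50 (SE 0.577, adjusted p = 0.0102). The peroxiredoxin gene Prx6c fell by 3.86 on the log2 scale (SE 0.281, adjusted p = 0.00673). The glutathione S-transferase gene GstT3 fell 10.1-fold (adjusted p = 0.00784) and the scavenger receptor gene Sr-CIV fell 10.5-fold (adjusted p = 0.0321). The remaining 5 of the 10 largest falls were CG11300 (log2 difference -4.12), Sclp (-3.75), CG14852 (-2.996), CG4593 (-2.75) and CG8087 (-2.49). Cyp4p2, Sclp and Sr-CIV were dim in the mutant, so their folds are uncertain, and with an offset of 50 before log2 their log2 differences were -2.35, -0.94 and -0.64. With that offset the value of nol was -3.46, of GstT3 -2.19, of CG14852 -1.69 and of CG8087 -1.61.

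CG12773 had the largest rise among the called genes, from a log2 signal of 2.68 ± 0.590 (SD, n = 3) in the control to 7.13 ± 0.0417 (SD, n = 3) in the mutant, a 21.7-fold difference (log2 difference 4.44, SE 0.330, limma adjusted p = 0.00673). This fold is uncertain, since CG12773 was dim in the control, and with an offset of 50 before log2 the log2 difference was 1.75. CG4741 rose 15.4-fold (log2 difference 3.95, SE 0.506, adjusted p = 0.0189) on its brightest probe set. Another probe set of CG4741 had a log2 difference of -0.30 (adjusted p = 0.671). Tsf1, which encodes the secreted iron-binding protein transferrin, rose 6.65-fold, from 7.58 ± 0.384 (SD, n = 3) to 10.3 ± 0.305 (SD, n = 3) on the log2 scale (adjusted p = 0.00783). LManI, a lysosomal alpha-mannosidase gene, rose 6.58-fold (adjusted p = 0.00793). Mec2 rose 7.62-fold (adjusted p = 0.00784) and Cyp309a1, another cytochrome P450 gene, rose 6.39-fold (adjusted p = 0.0489). Sting, the innate immune sensor of cyclic dinucleotides, rose 5.60-fold (adjusted p = 0.0341). The others among the 10 largest rises were CG15784 (log2 difference 2.58), Kmn1 (2.56) and CG42663 (2.54). With the offset of 50 the log2 differences of CG4741, LManI, Kmn1 and CG42663 were 2.17, 1.15, 1.19 and 0.68, and CG42663 was no longer called (limma adjusted p = 0.0751). The call of Cyp309a1 was lost with median centring (adjusted p = 0.0606).

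**Figure D1:**
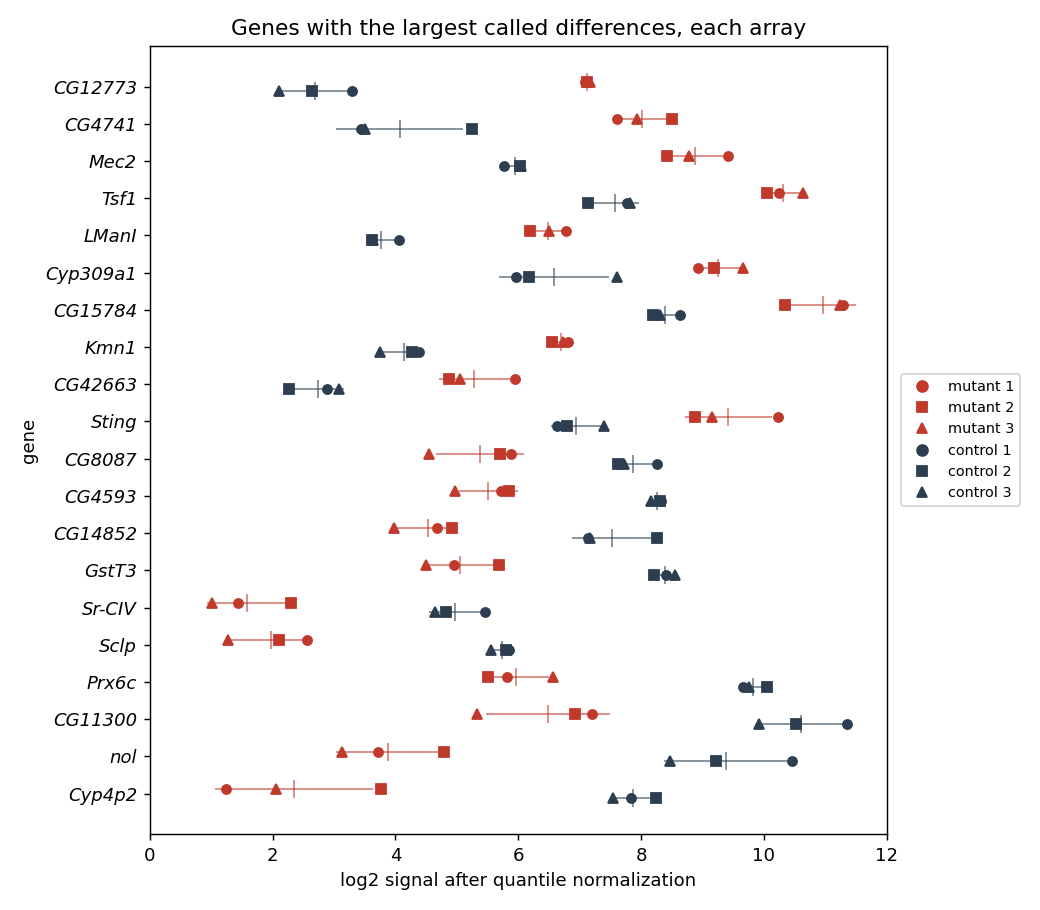
Log2 signal after quantile normalization (horizontal axis) of the 10 genes with the largest called rise and the 10 with the largest called fall (vertical axis). Each point is 1 array, red for mutant and dark for control, and the vertical tick with its bar is the mean ± SD of 3 arrays; for each gene the 3 mutant arrays lie on one side of the 3 control arrays.

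In all, 50 probe sets were higher and 40 lower in the mutant out of 11261 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The higher ones covered 38 named genes and the lower ones 35, and 15 of the 90 had no single gene name in the annotation used. The median fold was 3.76 among the higher and 3.70 among the lower probe sets, and the smallest called fold was 1.84. On each of the 90 the mutant arrays were separated from the control arrays. Of all tested probe sets 25.4% were separated, where chance gives 10% on average. Probe sets vary together between arrays, so the share in 1 split can lie far from 10% without a genotype effect. At an unadjusted p under 0.05 (limma) there were 2435 probe sets, 1108 of them higher and 1327 lower. This number does not by itself show a further genotype difference. Mutant arrays 1 and 3 with control array 3, set against the rest, gave 2350. Calls without normalization take no account of a probe set's own spread between arrays, because limma then gave every probe set the variance of the trend. Without normalization the split was 103 higher and 200 lower, and with median centring 23 higher and 41 lower. The median log2 difference of all tested probe sets was then -0.26 and -0.23, against -0.01 after quantile normalization. The counts of higher and lower probe sets were 22 and 14 without mutant array 1, 1320 and 1567 without mutant array 2, 6 and 7 without mutant array 3, 9 and 3 without control array 1, 0 and 0 without control array 2 (limma, 1400 at an unadjusted p under 0.05) and 28 and 11 without control array 3.

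Genes of oxidative phosphorylation, the main group of interest for a PGC-1 homologue, were lower in the mutant as a group. The median log2 difference over 56 genes was -0.72, with 55 of the 56 below 0 (camera, adjusted p = 6.0e-09 over 37 lists; adjusted p = 0.617 with an estimated correlation). None of the 56 passed the limma adjustment over all probe sets, none passed when adjusted over the list alone, and 20 were lower and 1 higher at an unadjusted p under 0.05. The lower signal came from mutant arrays 1 and 3, whose list means relative to the control mean were -1.12 and -1.07. Mutant array 2 was at 0.11, and the control arrays were at 0.14, 0.02 and -0.16 (exact two-sided permutation test of the list mean, p = 0.3). Without mutant array 2 the median was -1.15, and without mutant array 1 it was -0.52. The GAPDH ratio of 3-prime to 5-prime signal given above was also higher on mutant arrays 1 and 3 than on every control array, and on mutant array 2 within the range of the control arrays. The eIF4A ratio did not follow this order: on mutant arrays 1, 2 and 3 it was 1.78, 1.44 and 1.40, above every control array each time. The actin ratio parted the same arrays in the opposite direction. It was 0.10, 0.22 and 0.12 on mutant arrays 1, 2 and 3, against 0.19 to 0.39 on the control arrays. The fry test of limma, which asks whether the genes of a list move on balance one way, gave an adjusted p of 0.355. No call of any list held with an estimated correlation. On the same arrays the mean log2 signal of 6 salivary glue genes was 12.1, 9.34 and 12.1 in the mutant and 2.02, 1.52 and 11.03 in the control.

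By complex, the medians were -0.79 for complex I (26 genes, adjusted p = 3.0e-06), -0.80 for complex IV (8 genes, adjusted p = 0.0137) and -0.57 for ATP synthase (12 genes, adjusted p = 0.00345), each with an adjusted p = 0.617 with an estimated correlation. Complex II, with a median of -0.55 over 3 genes (adjusted p = 0.0917), and complex III, with -0.45 over 7 genes (adjusted p = 0.139), did not pass. Complex II was called with the replicate block (camera, adjusted p = 0.0444), and both were called with array weights (adjusted p = 0.0227 and 0.0268). The call of complex IV was lost without mutant array 3 (median -0.52, adjusted p = 0.110). With the mean of the Sgs glue genes as a covariate, chosen after the data were seen, the calls of complex IV (median -0.39, adjusted p = 0.291) and ATP synthase (-0.33, adjusted p = 0.121) were lost, and the median of complex III turned to 0.098 (adjusted p = 0.872). That of complex I was then -0.48 (camera at the preset correlation, adjusted p = 0.00284). No correlation was estimated in the fit with the covariate. Without the covariate the estimate for complex I was 0.84, so this p cannot show that its difference outlasts the covariate. Without mutant array 2 the medians were -1.23 for complex I, -0.83 for complex II, -0.75 for complex III, -1.23 for complex IV and -0.89 for ATP synthase, and complexes II and III were then called (adjusted p = 0.0144 and 0.00637). ATP synthase was at -0.38 without mutant array 1. Without mutant array 3 complex II was at -0.35, and without control array 3 complex III was at -0.68. Adjusted over the list alone, 1 gene passed in complex II, SdhD, and none in the other 4 complexes; over all probe sets none passed in any. ND-ACP passed over all probe sets without normalization (log2 difference -1.91, limma adjusted p = 0.0472). Without mutant array 2 many subunits passed, among them ND-ACP, ND-SGDH, SdhD, Cyt-c1, COX4, COX5B and ATPsynO (limma adjusted p from 0.000496 to 0.00321). This was not particular to them: 2887 of 11261 probe sets were then called, and 95 of the 117 named genes not called before. Mutant array 2 was the mutant array whose oxidative phosphorylation mean lay among the control arrays, so leaving it out favours a difference. Among single subunits, the log2 differences were -1.51 for ND-ACP (SE 0.404, limma adjusted p = 0.148), -1.22 for ND-SGDH (adjusted p = 0.153) and -1.06 for SdhD (adjusted p = 0.165). They were -0.90 for COX4 (adjusted p = 0.178), -0.61 for Cyt-c1 (adjusted p = 0.201) and -0.71 for ATPsynO (adjusted p = 0.207). ND-15, named as a complex I subunit, was the exception with a log2 difference of 0.77 (adjusted p = 0.166).

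Other mitochondrial groups gave lower medians as well, again from mutant arrays 1 and 3. On mutant arrays 1, 2 and 3 the list means relative to the control mean were -1.48, -0.18 and -1.27 for the mitochondrial ribosome, with control array 3 at -0.17. They were -0.57, -0.01 and -0.50 for genome maintenance, and -0.75, 0.03 and -0.57 for carriers. The ratios of 3-prime to 5-prime signal of these arrays, in the same order, were 2.10, 0.79 and 1.12 for GAPDH, 1.78, 1.44 and 1.40 for eIF4A and 0.10, 0.22 and 0.12 for actin. The proteins of the mitochondrial ribosome had a median of -0.96 over 68 genes, all 68 below 0 (camera, adjusted p = 6.4e-17; adjusted p = 0.617 with an estimated correlation). Of them 31 passed as lower when adjusted over the list alone, and none over all probe sets. With the Sgs mean as a covariate the median of this list was -0.59 (camera at the preset correlation, adjusted p = 5.3e-11). No correlation was estimated in that fit. Without the covariate the estimate for this list was 0.84, so that p cannot show that its difference outlasts the covariate. mRpL30 had a log2 difference of -1.47 and mRpL20 of -1.14 (limma adjusted p = 0.145 for each). Genes of mitochondrial genome maintenance, import and dynamics had a median of -0.29 over 18 genes (camera, adjusted p = 0.0363; adjusted p = 0.617 with an estimated correlation), none passing singly over all probe sets or adjusted over the list alone. Tom20, a subunit of the import receptor, had a log2 difference of -1.01 and TFAM, which packages mitochondrial DNA, of -0.57 (adjusted p = 0.157 and 0.205). The call of this list was lost without mutant array 1 (adjusted p = 0.0905), mutant array 3 (0.126), control array 1 (0.0662) or control array 2 (0.0506), with medians from -0.27 to -0.18, and was -0.45 without mutant array 2. It was lost also without normalization (-0.60, adjusted p = 0.0536), with the filter at the 60th percentile (-0.28, adjusted p = 0.0710) and with the Sgs mean as a covariate (-0.096, adjusted p = 0.377). Mitochondrial carriers and cytochrome c had a median of -0.41 over 9 genes (adjusted p = 0.0682), and the tricarboxylic acid cycle with pyruvate dehydrogenase had -0.32 over 13 genes (adjusted p = 0.370). Both lists were called lower under the other scalings: carriers without normalization (-0.98, adjusted p = 0.0368) and with median centring (-0.95, adjusted p = 0.0234), and the tricarboxylic acid cycle likewise (-0.84, adjusted p = 0.0368, and -0.81, adjusted p = 0.00792). Carriers were called also without mutant array 2 (-0.66, adjusted p = 0.00620) or control array 3 (-0.43, adjusted p = 0.0406). Without mutant array 2 the tricarboxylic acid cycle list was at -0.54 and was not called (camera, adjusted p = 0.217). In the tricarboxylic acid cycle list PCB, the pyruvate carboxylase gene, had a log2 difference of 0.43 (limma adjusted p = 0.136), which turned negative without normalization and with median centring. Neither list had a member past the adjustment over all probe sets or adjusted over the list alone.

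The cytosolic protein synthesis machinery was lower too. Cytosolic ribosomal proteins had a median of -0.97 over 39 genes, 38 of them below 0 (camera, adjusted p = 1.7e-16), and ribosome biogenesis and RNA polymerase I had -1.38 over 16 genes, all 16 below 0 (adjusted p = 5.0e-08). Aminoacyl-tRNA synthetases had -0.61 over 18 genes, 17 below 0 (adjusted p = 1.0e-06), and translation factors had -0.22 over 44 genes, 34 below 0 (adjusted p = 3.7e-04). With an estimated correlation each of the 4 had an adjusted p = 0.617. No member passed over all probe sets on the probe set used for the lists after quantile normalization. Without normalization RpS12 (log2 difference -1.79, limma adjusted p = 0.0387) and Nop60B (-2.10, adjusted p = 0.0218) passed, and with an offset of 50 RpS12 (adjusted p = 0.0494) and RpS27A (adjusted p = 0.04995) did. Without normalization the medians were -0.76 for translation factors and -1.07 for synthetases, or -0.51 and -0.81 relative to all probe sets. Adjusted over the list alone, 33 cytosolic ribosomal proteins, 15 biogenesis genes, 13 synthetases and 11 translation factors were lower and 1 translation factor was higher. RpS12 had a log2 difference of -1.22 (SE 0.222, limma adjusted p = 0.0675), Nopp140, a nucleolar protein, of -1.42 (adjusted p = 0.139), ArgRS of -0.86 (adjusted p = 0.104) and eIF3k of -0.94 (adjusted p = 0.0860). The means of the ribosomal protein list lay at -1.15, -0.36 and -1.12 relative to the control mean on mutant arrays 1, 2 and 3, with the ratios of 3-prime to 5-prime signal given above, and between -0.07 and 0.10 on the control arrays (exact two-sided permutation test of the list mean, p = 0.1, the smallest that 3 against 3 allows). DNA replication and cell cycle genes had a median of -0.55 over 15 genes, 14 below 0 (camera, adjusted p = 2.9e-04; adjusted p = 0.617 with an estimated correlation), with none passing singly over all probe sets or adjusted over the list alone. CycE had a log2 difference of -0.91 (limma adjusted p = 0.157). With the Sgs mean as a covariate the median was -0.28 for DNA replication (camera at the preset correlation, adjusted p = 0.0101) and -0.88 for ribosome biogenesis (adjusted p = 2.9e-06). No correlation was estimated in that fit. Without the covariate the estimates were 0.62 and 0.84, so these p-values cannot show that the differences outlast the covariate. The proteasome had a median of -0.03 over 39 genes (adjusted p = 0.405), with a mean of 0.16 and a test direction of lower; 0 members passed over all probe sets (limma, 9 at an unadjusted p under 0.05) and 1 was lower adjusted over the list alone. The median of the proteasome list was -0.57 without normalization (camera, adjusted p = 0.838). With the Sgs mean as a covariate the list was called lower at the preset correlation (-0.10, camera, adjusted p = 0.0461). Its gene Prosbeta5R2 was called higher without normalization (log2 difference 2.80, limma adjusted p = 0.0346).

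**Figure D2:**
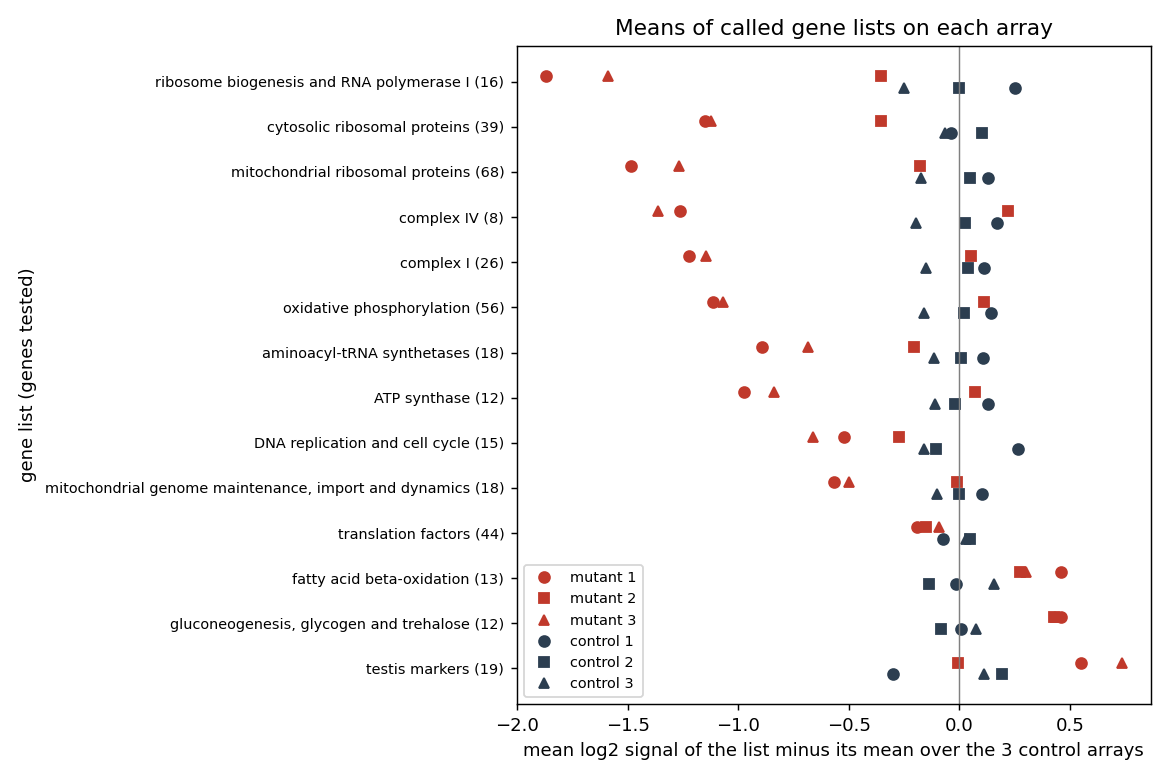
Mean log2 signal of each called gene list on each array (horizontal axis), relative to its mean over the 3 control arrays, with the number of genes tested in parentheses beside each list name (vertical axis); red points are mutant arrays and dark points control arrays. For oxidative phosphorylation mutant arrays 1 and 3 lie at -1.12 and -1.07 and mutant array 2 at 0.11; fatty acid beta-oxidation and gluconeogenesis lie above the control mean on all 3 mutant arrays here, and their medians turn negative without normalization and with median centring. The salivary gland list is not drawn.

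A pair of metabolic groups had higher medians after quantile normalization, and both turned negative without normalization and with median centring. Genes of gluconeogenesis, glycogen and trehalose had a median of 0.36 over 12 genes (camera, adjusted p = 0.0137; adjusted p = 0.617 with an estimated correlation; -0.11 without normalization). Fatty acid beta-oxidation had 0.33 over 13 genes (adjusted p = 0.0199; adjusted p = 0.617 with an estimated correlation; -0.21 without normalization). Relative to the median of all probe sets, the values without normalization were 0.14 and 0.05. Without mutant array 2 both calls were lost, with medians of 0.33 (adjusted p = 0.0703) and 0.30 (adjusted p = 0.0561), and without control array 2 that of beta-oxidation was lost (0.26, adjusted p = 0.0898). That of beta-oxidation was lost also with array weights (0.25, adjusted p = 0.0513) and with the Sgs mean as a covariate (0.18, adjusted p = 0.109). No member passed over all probe sets; adjusted over the list alone, 4 genes of the first list and 2 of the second were higher. Pepck1 and Pepck2, which encode phosphoenolpyruvate carboxykinases, had log2 differences of 1.79 (SE 0.383) and 1.47 (SE 0.344), with limma adjusted p = 0.104 and 0.125, and Pepck1 was called without control array 3 (2.23, adjusted p = 0.0330). The gene fbp, which encodes fructose bisphosphatase, had 0.61 (adjusted p = 0.104), and yip2 and Mtpbeta, of beta-oxidation, had 1.40 and 0.57 (adjusted p = 0.140 and 0.139). The lowest log2 difference under any alternative was 0.028 for fbp, 0.61 for yip2 and 0.006 for Mtpbeta. On the mutant arrays the gluconeogenesis list means were 0.46, 0.43 and 0.43 above the control mean, so that mutant array 2 did not stand apart there.

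Lsd-2, which encodes a perilipin of the lipid droplet surface, rose 2.89-fold (log2 difference 1.53, SE 0.164, limma adjusted p = 0.0102) after quantile normalization, from 10.3 ± 0.232 (SD, n = 3) to 11.8 ± 0.188 (SD, n = 3). This call was lost without normalization (log2 difference 0.96, adjusted p = 0.485) and with median centring (0.98, adjusted p = 0.139). Lsd-2 was the 1 gene of lipid synthesis and storage to pass, over all probe sets and adjusted over the list alone. The list's median was -0.09 over 17 genes (camera, adjusted p = 0.920), with a test direction of higher. In the same list ACC, acetyl-CoA carboxylase, had a log2 difference of -1.03 (adjusted p = 0.176) and the lipase gene bmm of 0.86 (adjusted p = 0.252), which turned negative with the Sgs mean as a covariate. Glycolysis had a median of -0.04 over 10 genes (adjusted p = 0.922), but was called lower with median centring (-0.55, adjusted p = 0.0180) and was at -0.57 without normalization (adjusted p = 0.0617). The median of insulin, TOR and FOXO genes was -0.02 over 14 genes (camera, adjusted p = 0.943). After quantile normalization no member of this list or of glycolysis passed, over all probe sets or adjusted over the list alone. Without normalization the glycolysis gene Hex-C was called lower (log2 difference -2.36, limma adjusted p = 0.00640). ImpL2, a secreted insulin antagonist, had a log2 difference of 0.75 after quantile normalization (limma adjusted p = 0.135).

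Detoxification genes changed in both directions. Of 60 cytochrome P450 genes 3 rose and 2 fell, and 13 and 9 did so when adjusted over the list alone. Cyp6w1 rose 4.12-fold (limma adjusted p = 0.0257), Cyp9c1 rose 2.85-fold (adjusted p = 0.0102) and Cyp4ac3 fell 3.57-fold (adjusted p = 0.0189), beside Cyp309a1 and Cyp4p2. Of 49 glutathione S-transferase and UDP-glycosyltransferase genes 2 rose and 2 fell, and 4 and 6 when adjusted over the list alone. Ugt301D1 rose 5.16-fold (adjusted p = 0.00779), Ugt36E1 rose 3.45-fold (adjusted p = 0.0263) and GstD2 fell 3.83-fold (adjusted p = 0.0189), beside GstT3. These folds are uncertain where a gene was dim: with the offset of 50 the log2 differences of Cyp6w1, Ugt36E1, Cyp4ac3 and GstD2 were 0.84, 0.91, -1.13 and -0.75. Some of these calls depended on the scaling. Without normalization those of Cyp9c1 (adjusted p = 0.441) and Ugt36E1 (0.103) were lost, and with median centring those of Cyp9c1 (0.151), Cyp6w1 (0.0527), Cyp309a1 (0.0606) and Ugt36E1 (0.0606). As lists they showed no shift to one side, with medians of 0.18 (camera, adjusted p = 0.370) and 0.09 (adjusted p = 0.928, with a mean of -0.14). Both medians turned negative without normalization and with median centring. Relative to the median of all probe sets they were 0.16 and 0.001 under both scalings. The fry test for change in either direction gave an adjusted p of 0.0116 and 0.00394. This was not particular to detoxification genes. The same fry test gave an adjusted p of 0.0116 each for gluconeogenesis, for antimicrobial peptides with immune response, and for fat body storage. It gave 0.0128 for trachea and 0.0418 for translation factors.

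Of the other lists of fat body function, oxidative stress defence had a median of -0.35 over 11 genes (camera, adjusted p = 0.425), autophagy 0.23 over 20 genes (adjusted p = 0.0917), and heat shock and chaperones 0.05 over 6 genes (adjusted p = 0.568). The medians of the others were, for the ecdysone response, 0.31 over 10 genes (adjusted p = 0.263) and, for antimicrobial peptides with immune response, -0.22 over 10 genes (adjusted p = 0.920). No member of these 5 lists passed over all probe sets, and 1 immune gene, BomS2, passed as higher when adjusted over the list alone (log2 difference 2.44, limma adjusted p = 0.0945; called without normalization, adjusted p = 0.0450). PGRP-SB1, of the same immune list, was called lower without normalization (log2 difference -2.14, limma adjusted p = 0.0176). Autophagy was called higher without mutant array 3 (median 0.16, camera, adjusted p = 0.0409). With 1 array left out, the medians ran from 0.11 to 0.53 for the ecdysone response and from -0.30 to -0.03 for the immune list. They ran from -0.04 to 0.29 for heat shock and from 0.14 to 0.30 for autophagy. The medians of autophagy, heat shock and the ecdysone response turned negative without normalization and with median centring, where the median of all probe sets was also negative. Relative to that median, autophagy was at 0.21, the ecdysone response at 0.19 and heat shock at -0.20 under both scalings. Fat body storage and secreted proteins had a median of 0.08 and a mean of 0.82 over 8 genes (camera, adjusted p = 0.263). The median turned negative without normalization and with median centring, but was 0.19 relative to the median of all probe sets under both. Without normalization the list was called with a test direction of higher (camera, adjusted p = 0.0368). Tsf1 was the 1 member that rose, over all probe sets and over the list alone.

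Markers of another organ varied more between arrays than any list of fat body function. The 6 Sgs genes, which encode the glue proteins made by salivary glands late in the third larval instar, had a mean log2 signal of 12.1, 9.34 and 12.1 on the mutant arrays and of 2.02, 1.52 and 11.03 on the control arrays. The salivary gland list had a median of 5.72 over 9 genes (camera, adjusted p = 0.0363; adjusted p = 0.617 with an estimated correlation), with no member passing over all probe sets or adjusted over the list alone. Sgs7 had a log2 difference of 6.76 (SE 2.38, limma adjusted p = 0.184). Sgs3 and Sgs7, at log2 signals between -0.49 and 0.34 on control arrays 1 and 2, lay near the bottom of the signal range there. Without normalization, where the spread between arrays does not enter, Sgs7 (6.36, adjusted p = 5.4e-25), Sgs8 (5.34, adjusted p = 3.2e-17) and Fbp1 (3.81, adjusted p = 1.2e-08) were called, and Sgs7 was called without control array 3 (9.80, adjusted p = 0.0246). The call of this list was lost without mutant array 2 (median 6.64, adjusted p = 0.335), control array 1 (4.09, adjusted p = 0.0662) or control array 2 (3.65, adjusted p = 0.135). It was lost also with the filter at the 60th percentile (adjusted p = 0.0615), with array weights (adjusted p = 0.193) and with the Sgs mean as a covariate (-0.34, adjusted p = 0.291). Fbp1, a fat body gene that is switched on late in the third instar, followed the same arrays, with 13.1, 10.1 and 12.9 in the mutant and 6.68, 5.38 and 11.6 in the control (log2 difference 4.14, SE 1.57, adjusted p = 0.201). The testis list had a median of 0.48 over 19 genes (camera, adjusted p = 0.0220; adjusted p = 0.617 with an estimated correlation), with betaTub85D at 1.42 (limma adjusted p = 0.210). No member passed over all probe sets or adjusted over the list alone, and the call was lost without mutant array 3 (median 0.29, adjusted p = 0.113) or control array 1 (0.29, adjusted p = 0.107), and with the Sgs mean as a covariate (0.24, adjusted p = 0.177).

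**Figure D3:**
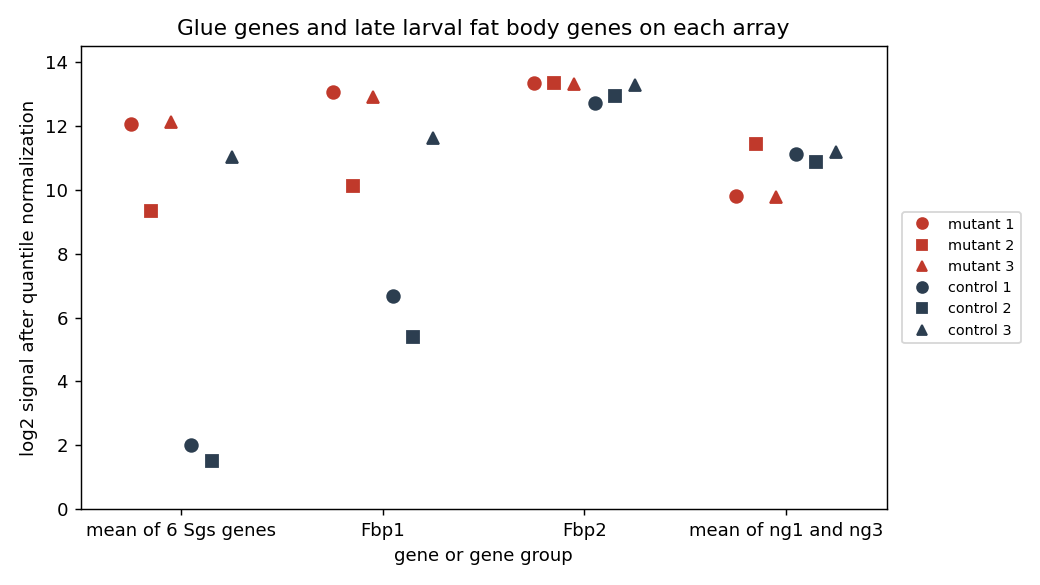
Log2 signal after quantile normalization (vertical axis) on each array for the mean of 6 Sgs glue genes, Fbp1, Fbp2 and the mean of the salivary gland genes ng1 and ng3 (horizontal axis); red points are mutant arrays and dark points control arrays. The Sgs mean is 2.02 and 1.52 on control arrays 1 and 2 and between 9.34 and 12.1 on the other 4 arrays, and Fbp1 parts the arrays likewise.

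The remaining markers of other tissues did not pass as lists. Medians were -0.11 for muscle (8 genes, camera adjusted p = 0.998), -0.61 for midgut (11 genes, adjusted p = 0.920), -0.03 for haemocytes (8 genes, adjusted p = 0.998, test direction higher), -0.30 for cuticle and epidermis (24 genes, adjusted p = 0.423), -0.21 for trachea (5 genes, adjusted p = 0.263) and -0.74 for Malpighian tubule (5 genes, adjusted p = 0.757). None of their members passed over all probe sets, and 1, the trachea gene pio, passed as lower when adjusted over the list alone (log2 difference -2.13, limma adjusted p = 0.0745; called without normalization and with median centring, adjusted p = 0.00427 and 0.0299; -0.80 with the offset of 50, adjusted p = 0.0263). The medians of 4 of these lists changed sign with 1 array left out, without a call: muscle ranged from -0.50 to 0.31, midgut from -1.17 to 0.14, haemocytes from -0.39 to 0.33 and Malpighian tubule from -1.53 to 0.27. The lowest were those without mutant array 1, or without control array 3 for haemocytes, and the highest those without mutant array 3 for muscle and Malpighian tubule and without mutant array 2 for midgut and haemocytes. Cuticle ranged from -0.47 without control array 3 to -0.07 without mutant array 2, and trachea from -0.42 without control array 2 to -0.13 without control array 3. The midgut list mean lay at -2.44 relative to the control mean on mutant array 2 and at 0.88 and -0.06 on mutant arrays 1 and 3, against -0.54 to 0.65 on the control arrays. Without normalization the midgut gene Mal-A6 was called higher (log2 difference 1.99, limma adjusted p = 0.0186). The cuticle genes Cpr47Eb (-2.06, adjusted p = 0.0175) and Lcp65Aa (-2.25, adjusted p = 0.0123) were then called lower.

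No called gene lay close to srl. Among the 50 protein-coding genes on each side of srl, 70 were tested and 0 were called by limma, against 70 of 8796 elsewhere (Fisher's exact test, two-sided, p = 1). The called genes were spread unevenly over the chromosomes: 9 of 3920 tested genes of the third chromosome, which carries srl, were called (0.230%). On the other chromosomes 62 of 4982 were called (1.24%; odds ratio 0.183, 95% interval 0.0797 to 0.370, Fisher's exact test, two-sided, p = 2.0e-08), a comparison chosen after the calls were seen. Without normalization the odds ratio was 0.894 (Fisher's exact test, p = 0.433).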

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

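The fits with the mean of the Sgs genes as a covariate, and without mutant array 2 and control array 3 together, were chosen after seeing the data; these 2 arrays were picked for lying near the other genotype, so their removal favours a difference. Each of the 90 called probe sets kept its sign in each refit in which it was tested. Their mutant and control arrays were all separated, so leaving arrays out or weighting them could hardly turn a sign. A change of filter or variance model leaves the difference itself as it is, so the kept signs say little about stability. The counts of higher and lower probe sets, 50 and 40, became 103 and 200 with values as deposited, 23 and 41 with median centring, 58 and 66 with the offset of 50, 16 and 14 without the variance trend, 1425 and 1710 with array weights, 11 and 7 at an adjusted p under 0.01, 1414 and 1488 without mutant array 2 and control array 3, and 0 and 0 with the Sgs mean as a covariate (limma, 456 at an unadjusted p under 0.05). For the stricter threshold its construction shows the cause, and for the others the cause was not tested. With 1 array left out they ranged from 0 to 1320 higher and from 0 to 1567 lower: 22 and 14 without mutant array 1, 1320 and 1567 without mutant array 2, 6 and 7 without mutant array 3, 9 and 3 without control array 1, 0 and 0 without control array 2, and 28 and 11 without control array 3. No filter, the filter at the 60th percentile, robust estimation and the 1.5 fold minimum left both counts within 1.5 times. Of the 90, 49 were still called with values as deposited, 44 with median centring, 29 with the replicate block and 90 without mutant array 2.

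With the replicate number as a block, 17 probe sets were higher and 14 lower. The deviations of arrays with the same number correlated at -0.20, -0.09 and 0.25 for numbers 1, 2 and 3, and mutant arrays 1 and 2 correlated best with control arrays 3 and 1, so the numbers were not taken to pair the samples.

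The median of oxidative phosphorylation genes stayed below 0 in all 19 alternatives, from -1.21 to -0.37. With 1 array left out it ran from -1.15 to -0.52. The call of this list was lost in 1 alternative, the estimated correlation. The median was then still -0.72 and the adjusted p was 0.617, because genes of the list vary together between arrays. The other 18 kept the preset correlation of camera, against an estimate of 0.83 for this list. Their calls therefore cannot show that the call is stable. The exact two-sided permutation test of the list mean gave p = 0.3, and fry gave an adjusted p of 0.355. Values as deposited turned the medians of fatty acid beta-oxidation to -0.21, of gluconeogenesis, glycogen and trehalose to -0.11 and of fat body storage and secreted proteins to -0.073 (this last list's mean was then 0.48 and its test direction higher, adjusted p = 0.0368). Median centring turned the first 2 to -0.18 and -0.087. The median of all probe sets was then -0.26 and -0.23, which covers only part of the turn: relative to it beta-oxidation went from 0.34 to 0.05 and gluconeogenesis from 0.38 to 0.14, and the cause of the rest was not tested. With the Sgs mean as a covariate the salivary gland median was -0.34, by construction, since the covariate holds its main genes. The planned fit of the srl level was not run. Low signal in one genotype limits the folds of rises and falls alike: with the offset of 50 the log2 differences shrank to -2.35 for Cyp4p2, -0.94 for Sclp, -0.64 for Sr-CIV, 1.75 for CG12773, 1.15 for LManI, 1.19 for Kmn1 and 0.68 for CG42663. Of 117 named genes that were not called, 14 were called with values as deposited, 1 with median centring, 3 with the offset and 95 without mutant array 2. With values as deposited limma's variance prior had infinite degrees of freedom, against 3.41 after quantile normalization, so a gene's own spread did not enter its p. Of the 27 named genes that were called, 24 were still called with values as deposited, 22 with median centring and 26 with the offset.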

Other observations

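The genes of this paragraph and the next lie outside the naming rule and were chosen after their values were seen; no test of a gene family was made, and the values are those after quantile normalization. Beside LManI, a second lysosomal alpha-mannosidase gene, LManII, rose 5.53-fold (log2 difference 2.47, SE 0.161, limma adjusted p = 0.00673, higher on 3 of 3 mutant arrays), while another, LManV, had a log2 difference of -0.19 (adjusted p = 0.817). Beside Prx6c, a second peroxiredoxin gene, Prx6a, fell 2.20-fold (adjusted p = 0.0489). Hmgs, the HMG-CoA synthase gene, fell 3.33-fold (adjusted p = 0.0341), and Yp3, a yolk protein gene, fell 3.42-fold (adjusted p = 0.0297). Tl, which encodes the receptor Toll, rose 1.97-fold (adjusted p = 0.0321) on 1 probe set, with a log2 difference of 0.26 (adjusted p = 0.839) on a dimmer one.

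RpL3 had 3 tested probe sets that differed in size and not in sign. The brightest had a log2 difference of -0.29 (limma adjusted p = 0.320), the next -1.79 (adjusted p = 0.0302, called) and the dimmest -1.44 (adjusted p = 0.140).

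In the 3 patterns that follow, the tests of the third chromosome, of the salivary gland genes ng1 and ng3 (also with the offset) and of Fbp1 were chosen only after the result was seen, and the criterion of the test with the Sgs covariate was tightened after its result was seen.

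The first pattern is the set of 90 called probe sets. A chromosome segment carried along with the srl1 insertion would put the called genes near srl, and the tables argue against it as the main source: 70 of 70 called protein-coding genes with a position lay outside the 200 genes on each side (54 on the side where the chromosome arm ends), and 0 of the 176 tested genes inside were called (Fisher's exact test, two-sided, p = 0.406). Differences between the stocks on the X, the second and the fourth chromosome may account for part of the calls and stay open: the odds ratio of a call on the third chromosome was 0.183 (Fisher's exact test, p = 2.0e-08), but genes at an unadjusted p under 0.05 that were not called, where the explanation asked for no such lack, had 0.840 (95% interval 0.757 to 0.932, p = 8.8e-04), and it was 0.224 with median centring and 0.894 without normalization. The 10 splits of the 6 arrays are too few for a share under 0.05: 1 split, the genotypes, called 90 probe sets, and the highest of the others called 0, while the split of mutant arrays 1 and 3 with control array 3 against the rest had 2350 at an unadjusted p under 0.05, close to the 2435 of the genotypes. Larval stage of the pools cannot be told apart from genotype for these calls. With the Sgs mean as a covariate, chosen after the data were seen, 0 probe sets were called (limma, 456 at an unadjusted p under 0.05). That fit does not decide, since the covariate differs with genotype and few residual degrees of freedom remain. RNA quality and the low signal of mutant array 1 were not tested as causes of the calls. An effect of srl1 itself stays open for every called gene.

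The second pattern is the glue genes, which differed between arrays of one genotype by up to 9.51 log2 units in the Sgs mean. Unequal amounts of salivary gland tissue would carry other gland genes along. Of these, ng1 and ng3 argue against unequal amounts as the only source: their mean range over the 6 arrays was 1.72 log2 units against 10.9 for the 6 Sgs genes. They cannot exclude unequal amounts beside another difference, since their mean was lowest on mutant arrays 1 and 3, where the Sgs mean was highest. Eig71Ee, also in the salivary gland list, followed the Sgs genes instead, with a range of 9.29. Its log2 signal was 12.9, 9.94 and 13.1 on the mutant arrays and 4.19, 3.77 and 12.7 on the control arrays. The gland genes thus do not all point one way. Several Sgs values on control arrays 1 and 2 lie near the bottom of the signal range, so 10.9 is no exact range. With an offset of 50 before log2 the mean ranges were 1.65 for ng1 and ng3 and 6.36 for the Sgs genes. Without the offset the mean of ng1 and ng3 was 11.1, 10.9 and 11.2 on control arrays 1, 2 and 3. On mutant arrays 1, 2 and 3 it was 9.79, 11.4 and 9.78, so it was lowest where the oxidative phosphorylation genes were lowest. Pools of different larval stage are a candidate explanation, since Fbp1, which belongs to the fat body, ordered 4 of the 4 pairs of arrays of one genotype whose Sgs mean differed by over 1 log2 unit as the Sgs mean did. These pairs are not independent, since each holds mutant array 2 or control array 3. The mean of the salivary gland genes ng1 and ng3 lay between 9.78 and 11.4 on all 6 arrays, as some gland RNA in all pools would give. Unequal amounts of gland tissue, and srl1 larvae reaching that stage at another time, stay open.

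The third pattern is the lower signal of oxidative phosphorylation genes on mutant arrays 1 and 3. Stage of the pools may contribute and cannot be told apart from genotype: with the Sgs mean as a covariate the genotype difference of the list mean went from -0.69 to -0.32, with a 95% interval of -2.20 to 1.56 on 3 residual degrees of freedom. That point estimate met the criterion as first set, which asked that more of the difference be lost than remained, while the tightened criterion asked also for an interval that excludes the size without the covariate, and this interval includes both 0 and -0.69. The low signal of mutant array 1 alone stays open as a part of it: without that array the median was -0.52, and only mutant array 3 then lay below the control arrays. RNA quality, untested, and an effect of srl1 stay open as well: of the ratios of 3-prime to 5-prime signal, GAPDH set mutant arrays 1 and 3 above every control array and mutant array 2 among them, while eIF4A was higher on mutant array 2 (1.44) than on mutant array 3 (1.40). Actin set mutant arrays 1 and 3 (0.10 and 0.12) below every control array and mutant array 2 (0.22) among them.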
